A study of Mus musculus with 6 samples.

How the data were processed

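Messenger RNA was sequenced from the whole kidneys of mouse embryos at E13.5. Per the labels, 3 libraries came from embryos carrying Foxd1Cre with 1 floxed and 1 null allele of Ptch1 (mutants), and 3 from littermates with 1 floxed and 1 wild-type allele (controls). RNA was extracted with a Qiagen micro column kit and libraries were made with an mRNA-seq kit, per the labels' protocols. Trim Galore, STAR 2.6.0c, HTSeq 0.6.1p2 and DESeq2 were the authors' tools and mm10 was the genome build, per the submitters' processing notes, which give no role or order for them. Whether the authors counted reads by strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

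The deposited table held 22394 genes. Its 6 library columns held FPKM made by the authors, that is, reads scaled to gene length and to library depth. No header names that unit. It was taken from the values, which were whole reads divided by a size factor per library and by a length per gene. The deposited table also held the authors' mean normalized signal per gene, their log2 fold change with its standard error, the test score (the Wald statistic) and the p-value with its adjusted form, per the file headers. Multiplying each gene's deposited FPKM by its mean normalized signal over its mean FPKM removed the gene length and gave size-factor normalized counts. Of the 134364 values obtained in this way, 100% were whole multiples of 1 step per library to within 1e-06 of a read. The steps gave each library's depth as 21644399, 24962204 and 25416896 reads in controls 1 to 3, and 21015151, 13261588 and 47847925 reads in mutants 1 to 3. One read was worth 0.498 normalized counts in the deepest library and 1.78 in the shallowest. The lowest total of any gene over the 6 libraries was 10 reads. No gene with fewer reads was in the table.

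The main test was limma 3.58.1 in R 4.3.3 with an intensity trend and no covariate. It was applied to log2(normalized count + 1) of the 16933 genes with a normalized count of at least 10 in 3 or more libraries. The tests, thresholds, gene lists and naming rule were chosen before the data were examined, for normalized values of a unit not yet known. The conversion to normalized counts was chosen once the unit had been seen, since the same cutoff on FPKM would depend on gene length. Applied to the deposited columns as they stand, the fixed rule is the fit on FPKM with a minimum of 10. That fit called 15 genes. Benjamini-Hochberg adjusted p-values under 0.05 were taken as calls. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. No count model was fitted, although the whole reads recovered would have allowed one. The authors' deposited table served as the count-based counterpart.

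For 35 fixed gene lists (kidney, stromal, vascular and other cell types, signalling pathways, and technical groups), limma's camera with a preset inter-gene correlation of 0.01 tested whether a list moved against all other genes. Camera with an estimated correlation and fry were run beside it. Counts of list members were also adjusted over the list alone. That adjustment was not corrected over the 35 lists, so a rise or fall on it is weaker evidence than a call over all genes. Older gene symbols were matched through RefSeq synonyms. Synonyms that are the symbol of another gene were not used. A list's score in a library is the mean over its tested members of log2(normalized count + 1) minus the mean of the 3 controls.

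The genes named follow a fixed rule. Ptch1, Gli1 and Foxd1 were always named. To these were added the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose mean normalized count was at least 50. Predicted genes, pseudogenes and the sex-linked list (Xist, Tsix and a few Y-linked genes) were left out. Other genes on the X chromosome, such as Slc38a5, stayed in. Up to 4 called members of each list with the smallest p were also named, and list members that were not called were given with values. Any gene outside the rule is marked where it is named. Gene positions came from GENCODE M21, whose build GRCm38 is the same assembly as mm10, and 22355 identifiers (99.8%) had one. FPKM are given as mean ± SD over the libraries of a group.

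The test was run first on simulated counts drawn from the means of the real genes, with 200 of 16863 genes changed. For the comparison of 3 mutant with 3 control libraries, 49.0% of genes changed 2-fold and 88.4% of genes changed 4-fold were recovered, and 7 of 145 calls (4.83%) were false. Camera called 2 lists in these counts, where the podocyte list alone had been shifted and 34 lists had not. Some of the 34 may hold changed genes. The simulated spread was the within-group variance of these libraries averaged over genes of similar mean, with a fixed value for the lowest genes. Genes were drawn independently and no library was made to stand apart. The recovered shares are therefore upper guides, and the false share sets no upper limit on false calls in the real data.

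The alternatives planned were TMM and upper-quartile rescaling, no filter and a filter of 50, limma-voom on the recovered reads, a robust fit, and pseudocounts of 0.5 and 5. Also planned were a replicate block, fits without haemoglobin and mitochondrial genes or without the listed sex-linked genes, and a minimum absolute log2 fold change of 1. Each library was also to be left out in turn. DESeq2 and edgeR on the recovered reads were also planned and were not run. After the data were seen, FPKM as deposited with minimums of 10 and 1 and estimated library weights were added. Of these, FPKM with a minimum of 10 is the fixed rule applied to the columns as deposited. The groups share sample numbers, but nothing in the labels pairs the libraries.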

Results

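The data were 6 RNA-seq libraries of whole mouse kidneys at E13.5, when the ureteric bud is branching and the first nephrons are forming. The kidneys of 3 mutant embryos were set against those of 3 control littermates. In the mutants, Cre recombinase was expressed from Foxd1, a transcription factor gene of the renal stromal progenitors, and Ptch1 was floxed on 1 allele and null on the other. Ptch1 encodes the receptor that keeps the Hedgehog pathway off when no ligand is bound, so the comparison asks how the kidney transcriptome differs when that brake is removed from the Foxd1 lineage. By the genotypes given, the groups also differed in carrying Foxd1Cre and in a null Ptch1 allele in every cell, and these differences cannot be separated from loss of Ptch1 in that lineage. Depth ranged from 13261588 reads (mutant 2) to 47847925 reads (mutant 3), and Spearman correlations between libraries were 0.969 to 0.989 within controls and 0.984 to 0.991 within mutants, against 0.969 to 0.987 between the groups. On the first principal component (39.4% of the variance) control 2 lay at 75.8 and the other 5 libraries at -24.6 to 8.49, so that axis did not separate the genotypes. The design text describes kidneys of 3 mutant mice and control littermates, so p-values were taken to measure the spread between mice. That each library came from 1 mouse was not tested. By the X-linked RNA Xist and the Y-linked gene Ddx3y, controls 1 and 3 had a female pattern, while control 2 and all mutants expressed Ddx3y (values below). Sex was therefore not balanced between the groups, beside the differences in genotype. Mutant 3 had more Xist than the other mutants, beside Ddx3y.

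In limma over all genes, 6 of 18 Hedgehog target genes and 4 of 18 endothelial genes rose in the mutant kidneys, and 4 of 10 skeletal muscle genes fell. These lists passed camera as sets, but not with an estimated correlation (adjusted p = 0.512, 0.176 and 0.441). Among called genes with a mean normalized count of at least 50, the largest changes were in Foxf2, Hhip and Acta1. The forkhead gene Foxf2 was nearly absent from controls and the skeletal actin gene Acta1 nearly absent from mutants. The Hedgehog binding protein gene Hhip was low in controls (mean 75.9 normalized counts). The targeted gene itself was higher in the mutants. Ptch1 (ENSMUSG00000021466.12, chromosome 13, 63508328 to 63573598, GRCm38) rose from 7.92 ± 0.331 FPKM in controls to 29.7 ± 6.17 FPKM in mutants (SD, n = 3 each), a log2 fold change of 1.89 (SE 0.16, limma adjusted p = 0.00443). Ptch1 is also transcribed in response to Hedgehog signalling, and a value over the whole gene does not show whether the floxed exons were removed, so this rise does not check the deletion. Foxd1, whose locus drives Cre, was at 63.2 ± 27.7 FPKM in controls and 49.4 ± 12.8 FPKM in mutants, and the groups overlapped (log2 fold change -0.27, SE 0.36, limma adjusted p = 0.782).

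Genes known to respond to Hedgehog signalling were among the largest rises in the data. Of 18 listed targets, 6 rose in the test over all genes, and 9 rose and 1 fell when adjusted over the list alone. The list as a set was higher in mutants (camera adjusted p = 8.83e-08, adjusted p = 0.512 with an estimated correlation, fry adjusted p = 0.122). Hhip, a membrane protein that binds Hedgehog ligands, rose from 0.351 ± 0.108 to 19.4 ± 3.37 FPKM (56.2-fold, log2 fold change 5.81, SE 0.25, limma adjusted p = 9.17e-05). The forkhead gene Foxf2 was near the detection floor in controls, at 0.0553 ± 0.0499 FPKM with 0 reads in control 2, and reached 14.8 ± 2.52 FPKM in mutants (log2 fold change 8.03, SE 0.63, limma adjusted p = 0.00443). Its relatives Foxf1 (1.34 ± 0.421 to 8.85 ± 4.47 FPKM) and Foxl1 (9.25 ± 1.99 to 29.2 ± 4.53 FPKM) rose as well. Gli1, a transcriptional effector and standard readout of the pathway, was higher in all 3 mutants than in any control, at 17.1 ± 4.33 against 28.9 ± 4.35 FPKM, but did not pass the test over all genes (log2 fold change 0.78, SE 0.20, limma adjusted p = 0.25, and 0.00975 adjusted over the list alone). In the authors' deposited table Gli1 had a log2 fold change of 0.88 and an adjusted p of 0.00227. Targets such as Ccnd1 (149 ± 32.8 and 123 ± 2.46 FPKM) and Ccnd2 (85.4 ± 13 and 90.5 ± 18.5 FPKM) did not pass. Among 20 listed components of the pathway, including the ligand gene Shh and the signal transducer Smo, none passed in limma over all genes or adjusted over the list alone (camera adjusted p = 0.945). Of these, 1 had an unadjusted p under 0.05 and the authors' deposited table called 2.

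**Figure D1:**
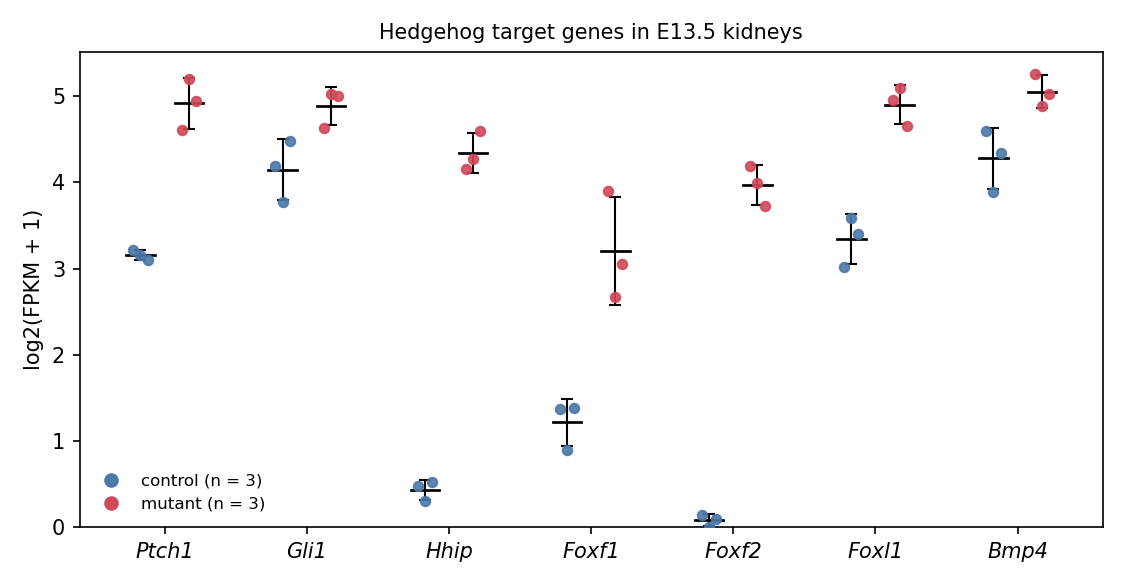
Expression of 7 Hedgehog target genes as log2(FPKM + 1) in each of 3 control (blue) and 3 mutant (red) libraries, with the mean (horizontal bar) and SD (error bar). All 3 mutant values lie above all 3 control values for each of these genes, with controls near 0 for Hhip and Foxf2; Gli1 and Bmp4 did not pass the test over all genes.

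Over all 16933 genes tested, 52 differed between mutant and control kidneys, 37 higher and 15 lower in mutants, and 1630 had an unadjusted p under 0.05. Groups did not overlap for 16.7% of the genes tested, where chance gives 10%, and for all 52 called genes. The authors' deposited table, from a count model, called 732 genes, 488 higher and 244 lower, and held 51 of these 52. All 729 of those 732 that were tested here had the same sign in limma, and 424 had an unadjusted p under 0.05. The number called depended on single libraries, with 15, 158 and 19 genes without control 1, 2 or 3 and 12, 9 and 13 without mutant 1, 2 or 3. Ptch1, Hhip, Foxf2, Cdkn2b, Acta1 and Myh3 were among the 8 genes called in each of these 6 fits, while the remaining called genes each lost their call in at least 2 of them. All 52 kept their sign.

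All 18 listed endothelial markers had positive fold changes with a median log2 fold change of 0.88. In limma 4 rose over all genes and 16 when adjusted over the list alone. The list moved as a set (camera adjusted p = 7.65e-21; adjusted p = 0.176 with an estimated correlation; fry adjusted p = 0.0188). Emcn, a sialoglycoprotein of venous and capillary endothelium, rose from 9.38 ± 0.944 to 23.3 ± 2.23 FPKM (log2 fold change 1.31, SE 0.13, limma adjusted p = 0.0105). The receptor tyrosine kinase Tie1 rose from 10.6 ± 0.444 to 22.1 ± 2.79 FPKM, the adhesion molecule Esam from 11.7 ± 0.905 to 23.0 ± 1.19 FPKM and the tight junction gene Cldn5 from 34.8 ± 3.19 to 63.4 ± 6.27 FPKM. Outside the list, Thbd, an anticoagulant receptor of the vessel lining and one of the 10 largest rises, rose from 1.14 ± 0.216 to 8.13 ± 3.24 FPKM. Pecam1 (16.8 ± 1.56 and 32.2 ± 5.75 FPKM) and the VEGF receptor gene Kdr (8.26 ± 1.72 and 16.3 ± 4.14 FPKM) passed over the list alone. The authors' deposited table called 12 of the 18 higher. The endothelial score was -0.03 to 0.02 in controls and 0.66 to 1.00 in mutants. Leaving out any 1 library kept the camera call.

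Most of the listed skeletal muscle genes that were tested were lower in mutant kidneys. Of 12 listed genes 10 were tested, and in limma 4 fell over all genes and 9 when adjusted over the list alone. The median log2 fold change was -2.81 (camera adjusted p = 1.86e-16, adjusted p = 0.441 with an estimated correlation, fry adjusted p = 0.0565). The skeletal actin gene Acta1 fell from 9.33 ± 4.64 to 0.208 ± 0.0937 FPKM (log2 fold change -5.26, SE 0.45, limma adjusted p = 0.00443) and the embryonic myosin heavy chain gene Myh3 from 5.44 ± 1.68 to 0.204 ± 0.145 FPKM (log2 fold change -4.85, SE 0.44, limma adjusted p = 0.00529). The myogenic transcription factor gene Myog fell from 4.8 ± 1.5 to 0.71 ± 0.343 FPKM and the fast myosin light chain gene Mylpf from 14.8 ± 5.24 to 3.27 ± 0.465 FPKM. Tnnt1 did not pass, at 14.5 ± 3.07 and 12.9 ± 1.77 FPKM. Outside the list, the sarcomeric genes Myh8, Actn2, Myh7 and Myl4 were among the 10 largest falls, with log2 fold changes of -3.28, -3.27, -2.81 and -2.44 and limma adjusted p of 0.0314, 0.0139, 0.0147 and 0.0158. Leaving out any 1 library kept the camera call, which was lost among genes of at least 10 deposited FPKM (adjusted p = 0.0594).

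**Figure D2:**
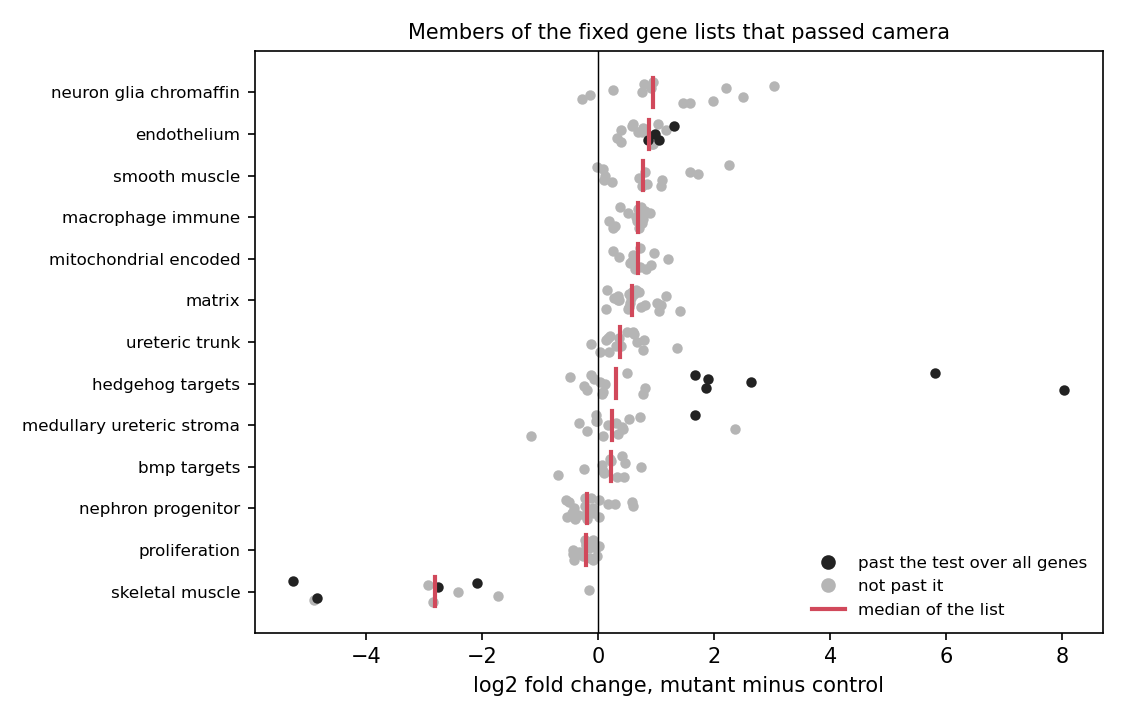
Log2 fold change, mutant minus control, of each tested member (points) of the 13 lists that passed camera, leaving out the sex-linked list; black points passed limma over all genes, grey points did not, and red bars mark list medians. Skeletal muscle genes sit far to the left of 0 (median -2.81) and the 18 endothelial genes all lie to its right (median 0.88). The Hedgehog target list has 5 of its 18 members below 0 and reaches up to Foxf2 at 8.03.

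Other large rises involved genes of varied function. Saa2, a serum amyloid A apolipoprotein gene, rose from 0.0522 ± 0.0453 to 2.01 ± 0.695 FPKM, and part of its reads may be shared with its near-identical neighbour Saa1, so its value is uncertain. Cdkn2b, which encodes the cell cycle inhibitor p15, rose from 0.329 ± 0.144 to 6.70 ± 1.49 FPKM (log2 fold change 4.28, SE 0.36, limma adjusted p = 0.00443). The amino acid transporter gene Slc38a5 rose from 0.387 ± 0.0688 to 3.69 ± 2.20 FPKM. Ntng1, a netrin-related axon guidance gene, rose from 0.968 ± 0.442 to 7.01 ± 1.46 FPKM. Fxyd7, a regulator of the sodium pump, rose from 2.65 ± 1.29 to 16.5 ± 2.59 FPKM, and Hapln3, a hyaluronan link protein gene, from 2.30 ± 0.624 to 15.2 ± 5.47 FPKM. Among the remaining falls, Plch1, a phospholipase C gene, went from 5.34 ± 0.219 to 2.93 ± 0.18 FPKM. The alpha globin gene Hba-a2 fell from 96.5 ± 30.0 to 3.51 ± 3.5 FPKM (log2 fold change -5.13, SE 0.58, limma adjusted p = 0.0147), while its near-identical copy Hba-a1 was at 1046 ± 207 and 1387 ± 342 FPKM (limma adjusted p = 0.583). Reads of this pair can be assigned to either copy, so the Hba-a2 value is uncertain.

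No member of the cortical stroma list (21 genes, camera adjusted p = 0.484) or of the list of secreted stromal signals (25 genes, camera adjusted p = 0.445) passed limma over all genes. At an unadjusted p under 0.05 there were 6 genes of each, and the authors' deposited table called 7 of each. Adjusted over the list alone, 3 cortical stroma genes rose and 2 fell, among them the growth factor receptor genes Pdgfra (29.4 ± 8.81 to 50.6 ± 7.22 FPKM) and Pdgfrb (16.0 ± 3.62 to 25.9 ± 4.59 FPKM), which rose, and the retinoic acid synthesis gene Aldh1a2 (279 ± 46.9 to 185 ± 16.6 FPKM), which fell. Among the secreted signals, Bmp4 (18.8 ± 4.72 to 32.4 ± 4.45 FPKM) and Wnt5a (5.70 ± 0.222 to 9.66 ± 2.72 FPKM) rose and the axon repellent gene Sema3a (7.11 ± 1.28 to 3.59 ± 0.979 FPKM) fell on that adjustment. The chemokine gene Cxcl12 was at 59.8 ± 26.4 and 115 ± 35.4 FPKM, with overlapping groups and a limma adjusted p of 0.456, and had an adjusted p of 0.000164 in the authors' deposited table. The smooth muscle list moved up as a set with no member past limma over all genes (6 at an unadjusted p under 0.05) and 4 of 14 adjusted over the list alone, including Tagln (8.46 ± 4.68 to 23.7 ± 8.36 FPKM) and Myl9 (56.9 ± 10.5 to 102 ± 11.5 FPKM) (camera adjusted p = 9.53e-06; adjusted p = 0.512 with an estimated correlation). Its score was 0.48 in control 2, above mutant 2 (0.36), and -0.36 and -0.12 in the other controls. The medullary and ureteric stroma list also moved up (camera adjusted p = 0.0138; adjusted p = 0.512 with an estimated correlation), with 1 of 16 genes, Foxl1, called, and 5 higher and 1 lower over the list alone. Its camera call was lost without control 1 (adjusted p = 0.0855) or control 2 (adjusted p = 0.0792), among genes of at least 10 deposited FPKM (0.0828) and with library weights (0.0634). All 22 extracellular matrix genes had positive fold changes (median 0.58, camera adjusted p = 7.49e-06; adjusted p = 0.647 with an estimated correlation), but none passed limma over all genes and only Lum passed when adjusted over the list alone. Of the 22, 4 had an unadjusted p under 0.05 and the authors' deposited table called 16. Control 2 had a matrix score of -0.97 against 0.38 and 0.59 in the other controls, and without it the median was 0.12 and the camera adjusted p was 0.14.

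The nephron progenitor and proliferation lists had small negative medians. The nephron progenitor list had a median log2 fold change of -0.19 (camera adjusted p = 0.0195; adjusted p = 0.512 with an estimated correlation). None of its 21 genes passed limma over all genes, 6 had an unadjusted p under 0.05 and the authors' deposited table called 2. Wt1 (63.6 ± 4.70 to 43.3 ± 0.708 FPKM), Eya1 (26.0 ± 2.65 to 18.9 ± 0.316 FPKM), Meox2 and Capn6 fell when adjusted over the list alone. The progenitor factor gene Six2 was at 144 ± 40.9 and 123 ± 3.94 FPKM with overlapping groups. This list's camera call was lost without control 1 (adjusted p = 0.331, median 0.03) or mutant 2 (adjusted p = 0.0583). Of 17 proliferation genes 16 had negative fold changes (median -0.21, camera adjusted p = 0.000377; adjusted p = 0.569 with an estimated correlation), with none past limma over all genes or adjusted over the list alone, 4 at an unadjusted p under 0.05 and 2 called in the authors' deposited table. The ureteric trunk list moved up (median 0.37, camera adjusted p = 0.012; adjusted p = 0.661 with an estimated correlation) with no member past limma on either adjustment, 2 at an unadjusted p under 0.05 and 1 called in the authors' deposited table. Its call was lost without control 1 (adjusted p = 0.254, median 0.20), control 3 (adjusted p = 0.178, median 0.25) or mutant 1 (adjusted p = 0.379, median 0.092). Its scores were 0.85 in control 2 and 1.04 in mutant 1 against -0.43 to 0.14 in the other 4 libraries, and the same libraries had the highest proximal tubule scores, 1.79 and 1.17 against -0.91 to -0.38.

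Markers of other cells and technical groups were measured beside these. The macrophage list moved up with 15 of 15 positive fold changes (median 0.68, camera adjusted p = 7.49e-06; adjusted p = 0.512 with an estimated correlation), as did the list of neuronal, glial and chromaffin genes (median 0.94, camera adjusted p = 7.19e-05; adjusted p = 0.512 with an estimated correlation), whose score was 2.30 in mutant 3 and 0.99 and 0.41 in mutants 1 and 2, against 0.54 in control 3. The latter call was lost among genes of at least 1 deposited FPKM (adjusted p = 0.0921). No member of either passed limma over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7 macrophage and 6 neuronal genes, and the authors' deposited table called 0 and 6. BMP target genes moved up (median 0.21, camera adjusted p = 0.0112; adjusted p = 0.512 with an estimated correlation), a call lost without control 1 (adjusted p = 0.129) or mutant 1 (adjusted p = 0.0575), with no member past limma on either adjustment, 4 at an unadjusted p under 0.05 and 0 called in the authors' deposited table. Mitochondrially encoded genes moved up (median 0.68, camera adjusted p = 0.0112; adjusted p = 0.661 with an estimated correlation). They took 0.367% of the reads of control 2 and 1.21% to 2.12% in the other libraries, and without control 2 their median was -0.083. With library weights the camera adjusted p was 0.131. No mitochondrial member passed limma on either adjustment or had an unadjusted p under 0.05, and the authors' deposited table called 3. The sex-linked list was higher in mutants (camera adjusted p = 0.0145; adjusted p = 0.512 with an estimated correlation), with 0 of 5 genes past limma over all genes and 4, all Y-linked, when adjusted over the list alone. This call was lost without control 1 (adjusted p = 0.12) and with no filter on low values (0.0555). Xist, transcribed from the inactive X chromosome, was at 72.9 and 53.3 FPKM in controls 1 and 3 and 0.0471 in control 2, and at 0.103, 0.206 and 6.19 in mutants 1 to 3. The Y-linked gene Ddx3y was at 0.0598 and 0.0177 FPKM in controls 1 and 3, at 17.8 in control 2 and at 13.9 to 16.2 in the mutants, so sex was not balanced between the groups for any gene group compared here. In all, 14 of the 35 lists passed camera, 11 up and 3 down, 0 passed with an estimated correlation, and fry called 1 by direction and 8 for change either way. Among the lists that passed camera, scores of the groups did not overlap for Hedgehog targets, endothelium, skeletal muscle and the sex-linked list, and overlapped for all others.

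**Figure D3:**
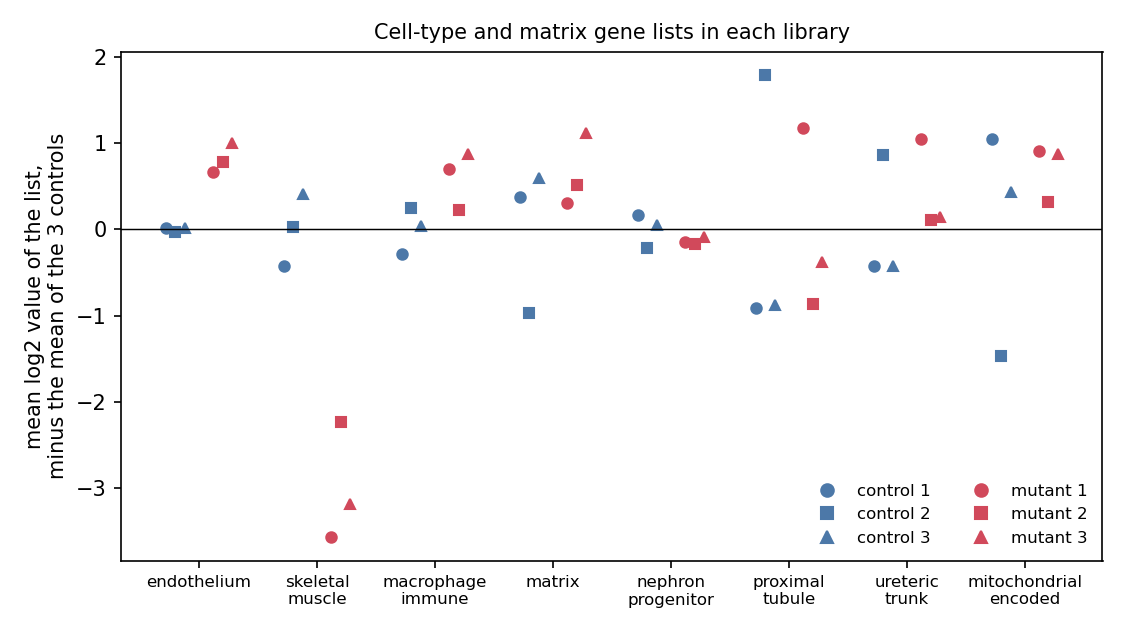
Scores of 8 gene lists in each control (blue) and mutant (red) library; a score is the mean of log2(normalized count + 1) over the list's genes minus the mean of the 3 controls, and marker shapes give the library number. The mutants lie above all controls for endothelium and below them for skeletal muscle (-3.57 to -2.23), while control 2 stands apart for matrix (-0.97), proximal tubule (1.79) and mitochondrially encoded genes (-1.47).

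The remaining 21 lists did not pass camera. Mural, renin and mesangial cells had an adjusted p of 0.25, early nephron 0.599, podocyte 0.31, proximal tubule 0.963, loop and distal tubule 0.103, ureteric tip 0.154, erythroid 0.154, adrenal cortex 0.829, gonad 0.503, cartilage 0.0952, liver 0.945 and mesothelium 0.4. TGF-beta signalling had a camera adjusted p of 0.0952, Wnt and beta-catenin targets 0.396, retinoic acid 0.552, p53 targets 0.45, hypoxia and glycolysis 0.945 and immediate early and stress genes 0.0976. Cortical stroma, secreted stromal signals and Hedgehog components are given above. In the TGF-beta list, adjusted over the list alone, Tgfb1 rose from 9.03 ± 1.58 to 20.4 ± 4.81 FPKM and the matricellular gene Ctgf from 3.21 ± 0.676 to 10.2 ± 3.91 FPKM, and Tgfbr2 also rose. On the same adjustment Mcam and Agtr1a rose in the mural list, Col4a4 in the podocyte list and Klf2 in the immediate early list. Wt1 fell in the mesothelium list. None of these genes passed limma over all genes. Without control 2, the only control with a male pattern, the proximal tubule list passed upwards (camera adjusted p = 0.00217, median 0.74 against -0.11 with it). The podocyte, early nephron, loop and distal tubule, ureteric tip, mural, erythroid, mesothelium, cartilage and TGF-beta lists each passed camera in at least 1 fit without a library, with adjusted p from 9.33e-05 to 0.0496.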

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

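The settings on deposited FPKM and the library weights were added after seeing the data, and so was the conversion to normalized counts in the main fit. The 52 genes called, the 37 higher and 15 lower, the 14 lists, Ptch1 and Gli1 stayed within 1.5 times or on the same side of the threshold under TMM and upper-quartile rescaling, no filter, a filter of 50, voom on the recovered reads, the robust fit, both pseudocounts, the fits without haemoglobin and mitochondrial or without sex-linked genes, and the minimum fold change, which gave 44 to 62 genes. The fit without sex-linked genes left out only the listed ones. Gm4017, a Y-chromosome pseudogene outside the naming rule and among the 37 higher genes, stayed in and kept its call. Gm4017 was at 0.249 ± 0.118 FPKM in controls, with 0.354 in control 2, and at 4.26 ± 2.05 FPKM in mutants. Ptch1 passed in all 21 settings of the fit (log2 fold change 1.74 to 2.04) and Gli1 in none (adjusted p 0.0619 to 0.685). Leaving out 1 library gave 9 to 158 genes, 6 to 112 higher, 3 to 46 lower and 10 to 17 lists. All 52 genes kept their sign in these 6 fits and 8 kept their call in each. Fits with 1 library fewer have less power, yet without control 2 the number rose to 158, which held all 52, and the cause was not tested. Control 2 is the only control with a male pattern, and all mutants expressed Ddx3y. In the fit without control 2, sex therefore cannot be told apart from genotype, for genes or for lists. With the replicate block, 17 genes were called, 13 higher and 4 lower, 16 of them among the 52. The deviations of same-numbered libraries had correlations of 0.00, -0.10 and 0.31, and control 1 and control 2 did not correlate best with their own number, so the pairing has no basis in the data. FPKM as deposited with a minimum of 10 gave 15 genes (13 higher, 2 lower) among 6586 genes tested, and with a minimum of 1 gave 33 (23 higher, 10 lower). Estimated library weights gave 380 genes (278 higher, 102 lower), with an estimate that stopped short of its convergence tolerance; the cause was not tested. Of the 14 lists, camera with an estimated correlation called 0 and fry called 1, endothelium. Without control 2 the proximal tubule list passed upwards (median log2 fold change 0.74, over the fits without 1 library -0.85 to 0.74) and the mitochondrially encoded list changed sign (median -0.083, over these fits -0.083 to 1.23), as the scores of control 2 for both lists, 1.79 and -1.47, make plain. No scaling moved the median of all genes by over 0.1. DESeq2 and edgeR on the recovered reads were planned but not run, although the whole reads recovered would have allowed them. In mutant 2, the shallowest library with 13261588 reads, 1 read was worth 1.78 normalized counts, so genes near 10 normalized counts rest on few reads there. How depth affected the calls was not tested.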

Other observations

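The tests of neighbouring genes, of the chromosome 13 loci, of muscle, endothelial and globin genes were chosen after the results were seen. Only the counts over other splits of the libraries were planned.

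Several genes that rose lie near each other. Starts and ends given here are the lower and upper coordinates of a gene, whatever its strand, and need not be where transcription starts. Foxf1 and Foxl1 start 43.6 kb apart on chromosome 8, with Foxc2 between them (start 121116171), which did not pass (log2 fold change 0.12, limma adjusted p = 0.744). Cdkn2a and Cdkn2b start 31.8 kb apart on chromosome 4, and Saa1 and Saa2 11.3 kb apart on chromosome 7 (GRCm38). On chromosome 13, 1700018A04Rik (31565492 to 31625792, its start 60.3 kb from that of Foxf2) ends just before Foxf2 starts (31625816). Cdkn2a, Saa1 and 1700018A04Rik fall outside the naming rule and were picked after their values were seen. 1700018A04Rik, a long non-coding RNA gene, was at 0 in all 3 controls and at 0.964 ± 0.257 FPKM in mutants. The hypothesis that neighbouring genes rise together more often than random genes stays open. There were 4 such pairs with starts within 100 kb among 37 risen genes, against at most 1 in 95% of 10000 random sets, but the pairs were noticed before they were counted, so the count restates what prompted it. Saa1 and Saa2 may share reads, and related genes in clusters are co-expressed in many tissues, which the random sets do not account for.

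The hypothesis that DNA flanking Ptch1 and Foxd1 from another strain changes nearby genes is argued against as a broad effect. Of 291 other tested genes within 10 Mb of either locus, 24 (8.25%) had an unadjusted p under 0.05, against 9.65% elsewhere (two-sided Fisher's exact p = 0.483; odds ratio 0.842, 95% interval 0.528 to 1.28), and 0 of the 291 were called in limma (9 in the authors' deposited table). Single genes changed by a linked variant are not excluded by this.

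The skeletal muscle list was lower in the mutants in camera, with 4 of 10 genes called in limma (adjusted p = 0.441 with an estimated correlation). One explanation is that control libraries held muscle cells that mutant libraries nearly lacked. The muscle genes Casq2, Mymk, Smyd1 and Myom2, outside the naming rule and picked after their values were seen, were also called lower. A second list of 27 muscle genes was taken, of which 23 were tested and at least Tnni1 and Cdh15 had been seen to be lower beforehand. Its median log2 fold change was -0.92 (quartiles -1.82 and -0.33). Of its genes 20 were negative, 16 lay below all controls in every mutant and 0 lay above all controls in every mutant. Groups did not overlap for 16.7% of all genes tested. In limma over all genes 0 of the 23 were called and 14 had an unadjusted p under 0.05, and the authors' deposited table called 5. The second list left out muscle genes already seen among the calls, such as Myh8, Actn2, Myh7 and Myl4, which draws its median towards 0. That median lies between the bounds set for either outcome, so the second list cannot decide and this explanation stays open. The sex of the embryos cannot be excluded either, since only control 2 has a male pattern: against that library the muscle list had a median log2 difference of -2.54 (quartiles -4.10 and -2.41). Whether such cells belong to the kidney or to tissue around it was not tested.

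The endothelial list was higher in the mutants in camera, with 4 of 18 genes called in limma (adjusted p = 0.176 with an estimated correlation). A smaller share of some other cell type would raise all remaining types alike: the endothelial score minus the mean score of all 12 other kidney lists was higher in mutants by 0.56 log2 units, within 2 pooled SD (SD 0.391), so this cannot be told apart. With the 8 of these lists that were chosen first, the difference was 0.62 (SD 0.194), beyond 2 pooled SD. The outcome therefore depended on which lists were taken. The smooth muscle score was higher by as much as the endothelial one (0.81 for both) and the macrophage score by 0.60, while 5 of the 12 lists, such as medullary stroma (0.33), lay below it by over 2 SD. Against control 2 alone, the endothelial list had a median log2 difference of 1.00 (16 of 18 positive), but 1 male control does not exclude the sex of the embryos. More endothelial RNA in mutants and a change within endothelial cells both stay open as hypotheses.

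Hba-a2 fell while no other erythroid gene passed limma. A loss of red blood cells as large as the fall of Hba-a2 is argued against by the other 11 erythroid genes. Their median log2 fold change was -0.22 (quartiles -0.34 and -0.07). A smaller loss is not excluded, since 10 of the 12 tested erythroid genes were negative. The erythroid list did not pass camera with all libraries (adjusted p = 0.154) but passed downwards without control 3 (0.0424) or mutant 3 (0.0185). The sum of Hba-a1 and Hba-a2 differed by 0.30 log2 units, but Hba-a2 held only 5.78% to 7.87% of that sum in controls (0.0972% to 0.341% in mutants), so reads divided differently between the near-identical copies cannot be told apart from a loss of Hba-a2. A strain variant at the locus was not tested.

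The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 52 genes against at most 8 in the others, 37 higher against at most 6, and 15 lower against at most 6; in each case 1 of the 10 splits gave a count as large. For the lists, 4 of the 10 splits gave at least the 14 of the real one, and the highest of the others gave 22, with controls 1 and 3 and mutant 2 against the rest. That split called 0 genes. Its list calls may come from a structure of the libraries other than genotype or from the preset correlation, which was not tested. A camera call alone therefore does not tie a list to genotype.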
